A study of Mus musculus with 2 samples.

How the data were processed

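Single-cell RNA was measured in 2 libraries of mouse knee articular cartilage, 1 after sham surgery and 1 after DMM, each pooled from 3 mice. Per the labels the tissue was digested with collagenase and dispase, and live cells (Calcein AM positive, DAPI negative) without CD45, Ter119 and CD31 were sorted onto a 10x Genomics 3' kit. The deposited values are UMI counts per gene and barcode as the authors' cell calling left them, with no normalisation, and every barcode held at least 500 UMIs. Per the file headers they came from Cell Ranger 7.1.0, whereas the submitters' processing notes list Cell Ranger 3.0.1 together with Seurat, STAR, HTSeq, DESeq2 and mm10. The sham library held 11362 barcodes and 106799078 UMIs (500 to 65956 per barcode), and the DMM library 11076 barcodes and 97346999 UMIs (500 to 76727). A bulk table of 6 per-sample columns was not used, because the column names match no sample, and the periosteum samples of the series were not analysed here.

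Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, and 532 sham and 390 DMM doublets called by Scrublet were removed. Counts were scaled to 10000 per cell, logged and reduced to 2000 variable genes and 30 principal components, without integration, then clustered over both libraries with 15 neighbours and a Leiden resolution of 1.0 (seed 1). Clusters were named with the suffix "-like" from 20 marker lists by the highest mean log2 fold of a list. They stayed unnamed where that score was under 0.75, where fewer than 3 markers passed, or where another list had more genes among the 10 leading genes; connective tissue was every cluster named as such a class, and each unnamed cluster where at least 50% of cells carried the collagen chaperone Serpinh1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Gene positions came from the GENCODE vM21 annotation (GRCm38), which held 99.8% of the 32285 features.

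UMIs were summed per class and library and given as CPM, counts scaled to the class total. Ratios carry exact conditional binomial 95% intervals, CPM values Poisson intervals and shares Clopper-Pearson intervals. Classes needed 50 cells per library, and sets of Procr cells 20. Each of the 24 gene lists is described by the median log2 ratio of its members with at least 50 UMIs and by its percentile among 10000 random lists of the same size, drawn from 20 bins of expression. Aldoa and Ddit3, 2 of the 473 list genes, were not measured because 2 identifiers share each symbol. No p-values, standard errors or counts of changed genes were computed, since each group had 1 library.

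Genes were named by rule: the 10 highest and 10 lowest ratios among genes with at least 100 UMIs, at least 50 CPM in the higher library, an interval without 1 and the same direction with median-of-ratios scaling; up to 4 members of each list; and Procr, Eng, Prg4, Col2a1, Acan, Sox9, Mmp3, Mmp13, Adamts5 and Col10a1. Mitochondrial, ribosomal and haemoglobin genes, unnamed gene models and blood markers were left out of the first part. For Procr cells, the rule took the 10 highest and 10 lowest by the smaller of both libraries' log2 ratios where these had 1 sign. The text names some of the genes that these rules gave.

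The filters, class markers, gene lists, naming rule, intervals and 15 of the alternatives were chosen before the data were examined. The name score of 0.75, the Serpinh1 rule, the choice of lists followed across settings (those outside the central 95% in either main class or in connective tissue), the removal of the trend on gene span, the comparison with erythroid-like cells and the removal of the top cell were chosen after. That comparison subtracted the log2 ratio over all erythroid-like cells together, which carries the makeup of their clusters and does not remove background RNA. The superficial cluster led by Serpina1e scored 0.795, close to that limit. Alternatives were other gene and mitochondrial limits, doublets kept, other Leiden resolutions, centring by library, median-of-ratios scaling, CPM without the most abundant genes, thinning to 2000 UMIs, other count minimums and Procr cells matched on depth. On simulated data with known ratios in 1 class, intervals excluded 1 for 100% of genes changed 2-fold and 72% of genes changed 1.25-fold, and they covered the truth for 95.2% of 11545 unchanged genes. The simulated counts were Poisson draws without variation between cells, as the intervals assume. Their coverage therefore says nothing about variation between real cells, mice or preparations.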

Results

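Knee articular cartilage cells of mice given sham surgery or surgical destabilisation of the medial meniscus (DMM), an operation that leads to osteoarthritis, were compared in 2 single-cell libraries, 1 per group, each pooled from 3 mice. The cells had been sorted as alive and negative for blood and endothelial surface markers. After filtering, 9491 sham and 9510 DMM cells were kept, with medians of 8051 and 7863.5 UMIs per cell. The cells fell into 31 clusters, of which 22 were connective tissue, holding 7686 sham cells (81.0%) and 8484 DMM cells (89.2%). With 1 library per group no test between sham and DMM was possible, so values are given for both libraries. Bracketed 95% intervals cover counting error only, not differences between mice or preparations, and those of UMI ratios leave out variation between cells. Intervals of rank correlations, given further below, come from resampling genes instead.

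Synovial lining-like cells, marked by Clic5 (a chloride channel family protein of lining fibroblasts), Htra4 and Col22a1, took a larger share of the DMM library. Chondrocyte-like cells with Col2a1 and Acan, the main collagen and proteoglycan of cartilage, took a smaller one. Lining-like cells were 4.57% [4.11, 5.06] of connective tissue cells in sham and 10.6% [9.96, 11.3] in DMM, 2.32-fold [2.05, 2.64] more. Chondrocyte-like cells were 21.5% [20.5, 22.4] in sham and 14.7% [13.9, 15.4] in DMM, 1.46-fold [1.36, 1.58] fewer. Superficial zone chondrocyte-like cells, which make the lubricant Prg4, held 20.4% [19.5, 21.3] in sham and 19.7% [18.8, 20.5] in DMM, a ratio of sham to DMM of 1.04 [0.968, 1.11].

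Within the superficial class, the cluster led by Serpina1e, Inhba and Col10a1 held 649 sham and 975 DMM cells, and the cluster led by Casr, Chst3 and Erg held 919 and 693. Hypertrophic chondrocyte-like cells led by Nrgn, Ihh (the signal of growth plate hypertrophy) and Panx3 were 4.92% in sham and 3.56% in DMM. Perivascular-like cells with Acta2 and Rgs5, genes of vessel-wall muscle and pericytes, were 4.97% and 3.76%, and fibroblast-like cells 17.0% and 15.3%. Fibroblast-like clusters went opposite ways, from 3.06% to 8.18% for the one led by Ctla2a, 7.39% to 4.11% for the one led by Ccl7 and 6.58% to 3.01% for the one led by Pi16 and Cd34. Osteoblast-like cells were 3.89% in sham and 5.39% in DMM, but their 2 clusters went opposite ways, 1.78% to 4.43% and 2.11% to 0.955%. Marrow stromal-like cells were 2.41% and 1.27%, and tendon or ligament-like cells 1.34% and 0.625%. Clusters that matched no class held 19.0% of connective tissue cells in sham and 25.2% in DMM. Among them, a cluster led by Postn and Mmp13 went from 5.97% to 10.9% and a cluster led by S100a4 and Tnn from 1.42% to 3.97%, while the other 3 went from 4.98% to 5.03%, 5.18% to 4.18% and 1.47% to 1.13%. The log2 ratio of the superficial share was -0.05 here and reached -1.04 when variable genes were centred by library. The osteoblast-like share changed direction with a minimum of 1000 genes or a Leiden resolution of 0.5, the hypertrophic share with centring and the fibroblast-like share with a limit of 5% mitochondrial UMIs. The lining-like and chondrocyte-like ratios kept their directions under all 8 such alternatives.

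**Figure D1:**
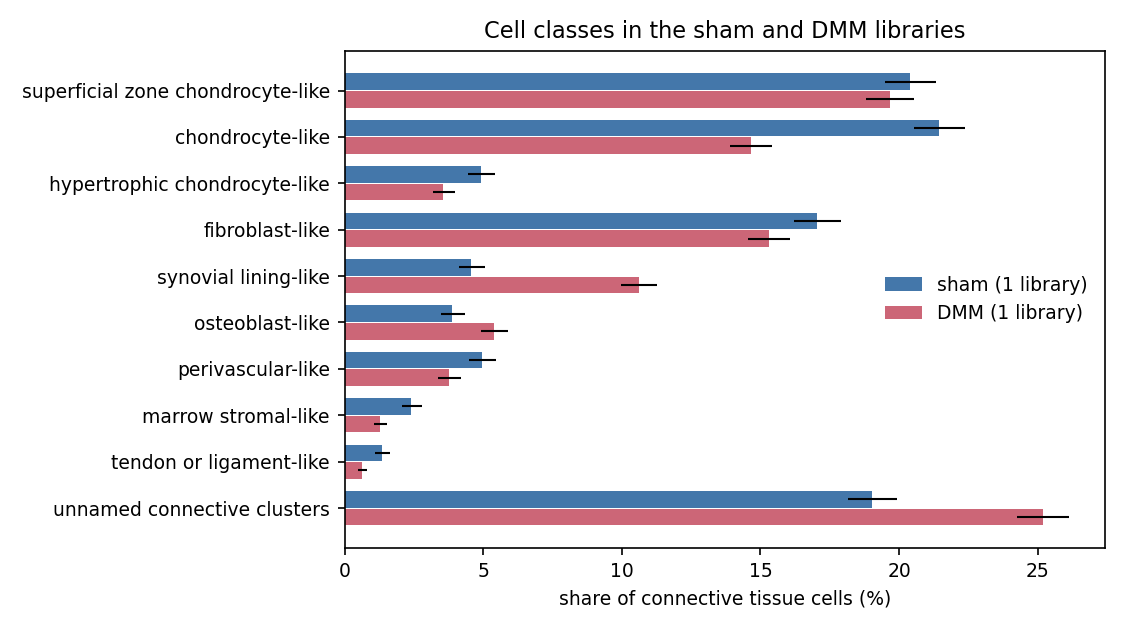
Share of connective tissue cells (%, horizontal axis) in each cell class of the sham and DMM libraries (1 library of 3 pooled mice each); bars are shares and lines their 95% Clopper-Pearson intervals for counting error. Synovial lining-like cells were 4.57% in sham and 10.6% in DMM, and chondrocyte-like cells 21.5% and 14.7%.

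In superficial zone chondrocyte-like cells of the DMM library, Spp1 (osteopontin, a mineral-binding matrix protein), Chil1 (a chitinase-like protein secreted by stressed chondrocytes), Mia (a small protein secreted by cartilage) and Lum (a collagen-binding proteoglycan) were higher. Igfbp5 (an IGF-binding protein), Myoc (a secreted glycoprotein), Itih5 (a hyaluronan-binding protein) and Thbs1 (a matrix glycoprotein that can activate TGF-beta) were lower. Spp1 was at 551 CPM in sham and 1472 in DMM, 2.67-fold [2.60, 2.74] higher. Chil1 was at 59.8 and 173 CPM, 2.89-fold [2.67, 3.12] higher, Mia at 123 and 244, and Lum at 116 and 283. Igfbp5 was at 576 CPM in sham and 162 in DMM, 3.55-fold [3.39, 3.72] lower. Myoc was 2.92-fold [2.66, 3.21] lower (119 to 40.9 CPM), Itih5 2.80-fold lower (165 to 58.8) and Thbs1 2.25-fold [2.18, 2.32] lower (849 to 377). These 8 genes had the same direction in both clusters of the class, with log2 ratios of 1.00 and 2.21 for Spp1 and -0.72 and -1.61 for Igfbp5 in the clusters led by Serpina1e and by Casr. The class ratio of Igfbp5 was beyond both of its cluster values, so it also carries the different cluster sizes in sham and DMM. Igfbp5 lies on chromosome 1 at 72857932 to 72874884 (GRCm38), Spp1 on chromosome 5 at 104435118 to 104441050.

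Prg4 itself was at 58103 CPM in sham and 65172 in DMM (log2 0.17), and the cartilage genes Col2a1 (0.07), Acan (-0.10) and Sox9 (0.02), the chondrocyte transcription factor, were close to equal in the superficial class. Among matrix proteases, Adamts5 (an aggrecan-cleaving enzyme) was at 52.2 and 33.0 CPM, and Mmp3 at 115 and 99.5. The ratio of the collagenase Mmp13 (-0.32 [-0.88, 0.23]) was not distinguishable from equal at this depth. Col10a1, a hypertrophy collagen, was at 1140 and 1668 CPM, with log2 ratios of 0.28 and -0.15 in the Serpina1e and Casr clusters, whose sizes differed between libraries. Tm4sf1 (a membrane protein) was 1.95-fold higher (141 to 274 CPM), Cryab (a small heat shock protein) 2.02-fold higher (137 to 277). Hhip (a Hedgehog inhibitor), Dgki (a diacylglycerol kinase) and Fbxl7 (a ubiquitin ligase part) were 2.20-, 2.36- and 2.07-fold lower. Hhip went opposite ways in the Serpina1e and Casr clusters, 0.46 and -0.87. Npy (a neuropeptide; 3.20-fold higher), Il11 (a cytokine of the IL-6 family; 2.23-fold) and Fxyd2 (a sodium pump subunit; 2.23-fold) changed direction when variable genes were centred by library, to -1.79, -2.68 and -1.95. For Npy, 1 cell held 35.2% of the UMIs in sham and 1 cell 18.6% in DMM.

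Erythroid-like cells, which should lack cartilage and connective tissue genes, were used to gauge background RNA in 4 clusters, held in different proportions in sham and DMM. Col2a1 was lower in DMM in all 4 (log2 -0.54, -0.59, -0.98 and -0.90) and Col1a1, a fibrous collagen, higher in all 4 (0.63, 1.27, 2.71 and 1.21). Col3a1, a second fibrous collagen, was higher in 3 of them (1.56, 3.90 and 1.83), with -0.33 [-0.92, 0.23] in the other. Prg4 went both ways, from 877 to 162 CPM in 1 cluster and from 94.2 to 186 in another, so its pooled fall from 425 to 173 CPM was not shared by all. Haemoglobin RNA in joint cells differed too. Hbb-bs went from 1715 CPM in sham to 643 in DMM in superficial, 2519 to 500 in lining-like and 1210 to 619 in fibroblast-like cells. In chondrocyte-like cells it was at 377 and 357 CPM. The 2.64-fold higher Col3a1 of the superficial class (35.7 to 94.2 CPM) lay within the range of levels in erythroid-like clusters, 10.6 to 46.8 CPM in sham and 27.5 to 167 in DMM. Genes of many cell types were also among the lowest ratios of the superficial class: Hnrnpa0 (an RNA-binding protein, 2.30-fold lower), Mbd2 (a methyl-CpG reader, 2.63-fold) and Brd1 (a chromatin reader, 2.60-fold).

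Of the 24 gene lists, the glycolysis and hypoxia, oxidative phosphorylation and antioxidant lists stood higher in DMM superficial cells, and the Wnt and the pain and nerve growth lists lower. Each list is given as the median log2 ratio of DMM to sham over its genes, with its percentile among 10000 random lists of similar expression. The hypoxia and glycolysis list was at 0.32 [0.26, 0.46] (percentile 99.98), with 18 of 21 genes higher, among them the glycolytic enzymes Eno1 (266 to 448 CPM) and Tpi1 (256 to 422) and the lipid droplet gene Hilpda (14.8 to 25.7). Oxidative phosphorylation was at 0.31 [0.29, 0.36] (percentile 100), led by Cox7a2 (177 to 264 CPM), Ndufa2 (109 to 161), Uqcrq and Cox5a, subunits of the respiratory chain. The antioxidant list was at 0.28 [0.24, 0.35] (percentile 99.9), with Prdx6 and Gpx4, which detoxify peroxides, and Sod1 and Hmox1 higher. Wnt signalling was at -0.52 [-0.65, -0.30] (percentile 0.34), with Dkk3 2.05-fold and the Wnt receptor ligase Znrf3 1.86-fold lower. The Wnt list holds ligands, receptors, target genes and inhibitors together, so its median gives no direction of pathway activity. The pain and nerve growth list was at -0.59 [-0.74, -0.39] (percentile 0.41). Its lower genes included the axon guidance cues Sema3c (1.98-fold), Ntn1 (1.86-fold) and Ntn4 (1.48-fold) , not pain peptides. In the Serpina1e cluster alone the Wnt (-0.24), pain (-0.12) and hypoxia (0.14) lists were inside the central 95% of random lists. In the Casr cluster pain was at -0.86 and hypoxia at 0.40, both outside it, and Wnt at -0.51 (percentile 2.53) just inside.

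The superficial hypoxia and glycolysis result stayed outside the central 95% under all 15 alternatives (0.15 to 0.54), and the Wnt result under 6 of 15. Pain and nerve growth was outside under 12 of 14 alternatives, the antioxidant list under 14 of 15 with a reversal to -0.12 when genes were centred by library. Oxidative phosphorylation was outside under 14 of 15, all but the comparison with the ratio in erythroid-like cells. That comparison left 0.07 (percentile 74.7). In the 4 erythroid-like clusters the list was at 0.10, 0.11, -0.03 and 0.23 (percentiles 98.5, 99.8, 85.5 and 98.8). Across 8600 genes of the superficial class the ratio of DMM to sham also fell with the span of the gene (Spearman rho -0.59, genes not being independent replicates), so long genes stood lower as a group. With that trend removed the pain list was at -0.19 (percentile 8.82). With CPM the median log2 ratio over well-counted genes was -0.14 in the superficial class, -0.15 in chondrocyte-like cells and -0.13 over connective tissue. Median-of-ratios scaling sets it near 0 and so puts every ratio higher.

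The other 19 lists were inside the central 95% in superficial cells, with some members far apart. Inflammatory cytokines and chemokines had a median of 0.01, with Ptgs2, the prostaglandin synthase (3.22 to 20.4 CPM), and Lcn2 (23.3 to 58.5) higher and Nos2, which makes nitric oxide (24.3 to 6.50), lower. Cartilage matrix was at -0.28, chondrocyte transcription factors at -0.19, superficial zone and lubrication at -0.19 and fibrous matrix at -0.19. Hypertrophy was at 0.09, and matrix degrading enzymes and inhibitors, called degrading enzymes below, were at -0.13. Signalling lists were at 0.06 for NF-kB, -0.18 for interferon, 0.08 for complement, -0.19 for TGF-beta and BMP with the growth factor Bmp5 lower (386 to 212 CPM), and -0.25 for Hedgehog, Notch and YAP, where all 11 genes were lower. The progenitor list was at -0.18 with Ly6a, a stem cell antigen of mouse mesenchyme, higher (10.0 to 31.1 CPM) and Pdgfra lower (33.3 to 19.0). Cell cycle was at -0.24, senescence and p53 at 0.08, unfolded protein response at -0.01, dissociation stress at -0.02, lipid metabolism at -0.24 with Fabp5, a fatty acid carrier, higher (13.8 to 40.3 CPM), and growth factors at -0.11 with Igf2 lower (12.3 to 1.88 CPM).

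**Figure D2:**
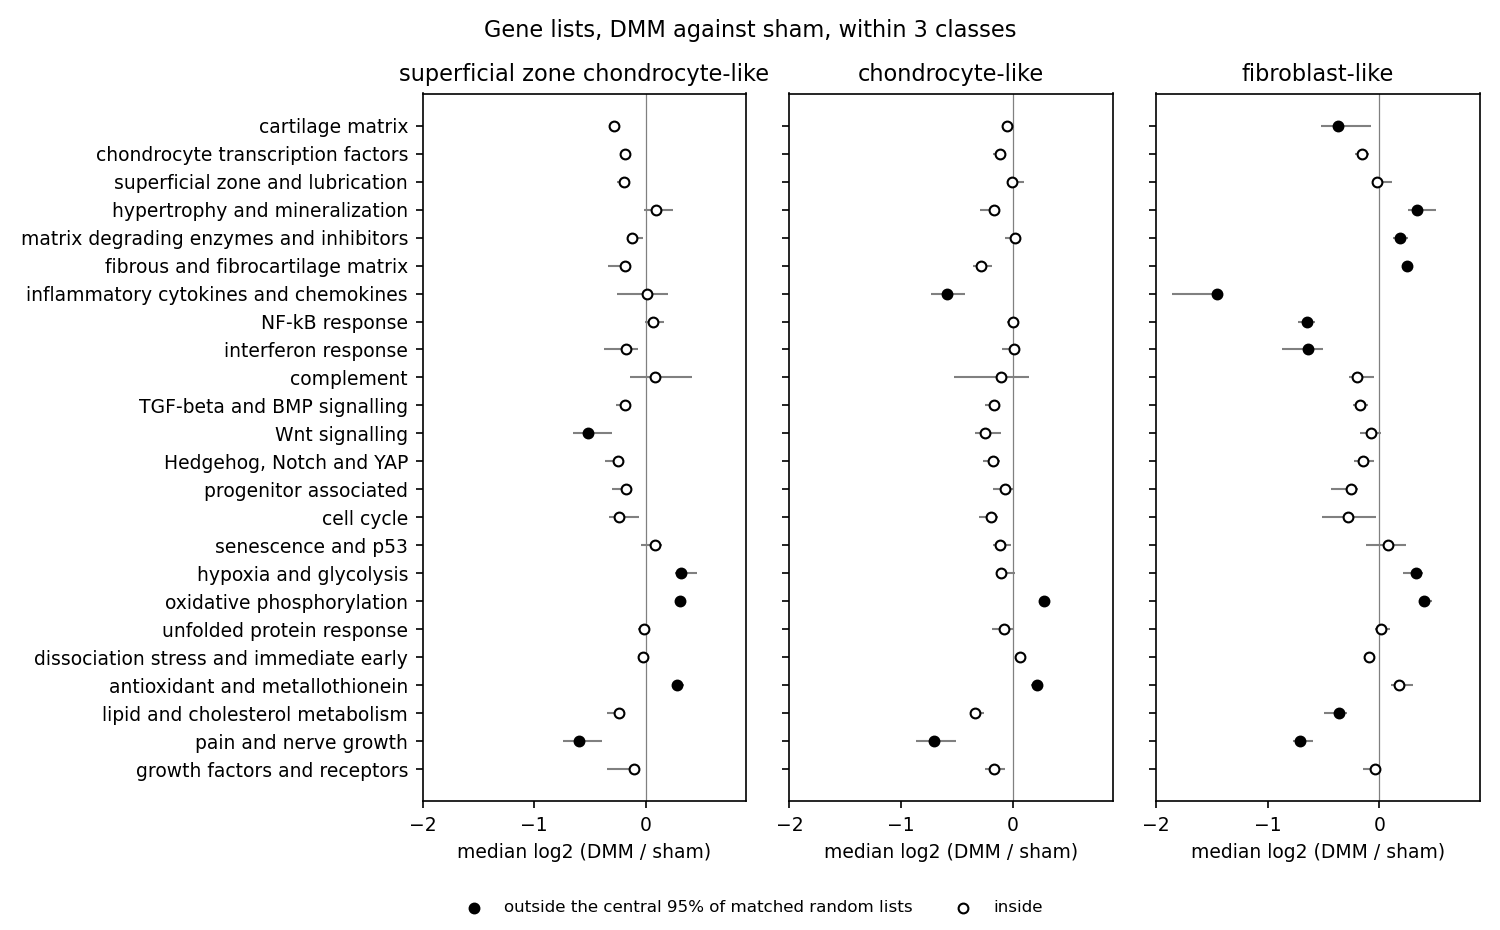
Median log2 ratio of DMM to sham (horizontal axes) of each of 24 gene lists in superficial zone chondrocyte-like, chondrocyte-like and fibroblast-like cells, 1 library per group; lines are counting intervals and filled points lie outside the central 95% of matched random lists. Oxidative phosphorylation was at 0.31, 0.28 and 0.40 in the 3 classes and the inflammatory list at 0.01, -0.59 and -1.46.

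In chondrocyte-like cells, Rrad (a small GTPase), Klf2 (a flow-responsive transcription factor) and Ndufa4l2 (a mitochondrial protein induced by low oxygen) were higher in DMM. Susd5 (a membrane protein) and Loxl4 (a collagen crosslinking enzyme) were lower. Rrad was at 168 CPM in sham and 294 in DMM, 1.75-fold [1.67, 1.82] higher, Klf2 at 187 and 327, and Ndufa4l2 at 67.6 and 104. Susd5 was at 488 and 261 CPM, 1.87-fold [1.81, 1.94] lower, Loxl4 1.81-fold lower (84.0 to 46.5) and the protease Adam12 1.80-fold lower. Col2a1 (-0.15), Acan (-0.05), Sox9 (-0.05), Mmp3 (0.10), Mmp13 (0.08) and Adamts5 (-0.12) were within 0.15 of equal on the log2 scale, Prg4 was at 410 and 580 CPM and Col10a1 at 19.3 and 11.7. Msmp, a microseminoprotein-like gene, had the lowest ratio (201 to 9.51 CPM), but 1 cell held 88.9% of its sham UMIs and without the top cell of each library its log2 ratio was -1.65. Crip1 was 1.75-fold and Col1a1 1.72-fold higher (49.4 to 85.1 CPM, against 39.8 and 106 in erythroid-like cells), and Hnrnpa0 was 2.16-fold, Mbd2 2.09-fold and F13a1 1.98-fold lower.

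Among lists in chondrocyte-like cells, pain and nerve growth was lower at -0.71 [-0.87, -0.51] (percentile 0.01), with lower genes including Slit2, an axon repellent (2.55-fold), and the neurotrophic factors Artn (1.80-fold) and Ntf3 (1.71-fold). Inflammatory cytokines and chemokines were at -0.59 [-0.73, -0.42] (percentile 0), led by Nos2 (6.22 to 1.73 CPM), Cxcl12 (17.5 to 10.4), Csf1 and Il11 (66.2 to 42.1). Oxidative phosphorylation was at 0.28 [0.23, 0.32] (percentile 100) and the antioxidant list at 0.22 [0.16, 0.26] (percentile 99.9), with the metallothionein Mt1 at 763 and 1155 CPM. The pain list stayed outside the central 95% under 13 of 14 alternatives, and the inflammatory list under 12 of 14, with -0.17 (percentile 41.7) over genes with at least 200 UMIs. Oxidative phosphorylation was outside under 14 of 15 and the antioxidant list under 13 of 15. Against the ratio in erythroid-like cells they were at 0.03 (percentile 58.3) and 0.14 (percentile 93.8), and the antioxidant list was at 0.16 (percentile 95.6) with the span trend removed. The erythroid-like ratio was pooled over clusters held in different proportions in sham and DMM, so it carries that makeup.

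The other 20 lists were inside the central 95% in chondrocyte-like cells. Matrix lists were at -0.05 for cartilage and -0.28 for fibrous matrix, where Tnc, a glycoprotein of injured matrix, was 3.39-fold lower (26.4 to 7.77 CPM). Chondrocyte transcription factors were at -0.11, lubrication at -0.00, hypertrophy at -0.17, degrading enzymes at 0.02, NF-kB at 0.01, interferon at 0.02 and complement at -0.10. TGF-beta and BMP were at -0.16 with the growth factor Bmp6 1.79-fold lower (145 to 80.8 CPM), Wnt at -0.24, Hedgehog, Notch and YAP at -0.18, and progenitor genes at -0.07 with the hyaluronan receptor Cd44 1.70-fold lower (292 to 172). Cell cycle was at -0.19 with the proliferation marker Mki67 lower (44.7 to 24.8 CPM), senescence at -0.11, hypoxia and glycolysis at -0.11, unfolded protein response at -0.08, dissociation stress at 0.07, lipid metabolism at -0.33 and growth factors at -0.16.

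Over all connective tissue cells, where a ratio also carries the share of each class, the monocyte attractants Ccl2 and Ccl7 and the proliferation genes Mki67 and Top2a were lower in DMM, and the proteases Mmp2 and Ctsk higher. Ccl2 was at 77.6 CPM in sham and 14.5 in DMM, 5.36-fold [5.02, 5.72] lower, and Ccl7 at 107 and 17.7. Both lead a fibroblast-like cluster that held 568 sham and 349 DMM cells. Lepr, a receptor of marrow stroma, was at 93.3 and 30.9 CPM. Among higher genes were the matricellular Ccn5 (21.5 to 56.1 CPM), the water channel Aqp1 (79.9 to 198), the Wnt modulator Sfrp2 (31.0 to 69.2) and the lining-cell gene Pla1a (35.9 to 125). Prg4 was at 15684 and 23287 CPM, Mmp3 at a log2 ratio of 0.53, Col2a1 at -0.64, Acan at -0.44, Sox9 at -0.28, Adamts5 at -0.19, Mmp13 at 0.07 and Col10a1 at -0.05.

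By list over connective tissue, inflammatory cytokines and chemokines were at -0.78 (percentile 0), with 16 of 21 lower, and lipid and cholesterol metabolism at -0.54 (percentile 0), with the sterol synthesis enzymes Idi1 (98.4 to 55.8 CPM) and Hmgcs1 (235 to 143) lower. The cell cycle was at -0.47 (percentile 0.03), with Mki67 (22.5 to 11.0) and Top2a (28.4 to 13.4) lower. A chondrocyte-like cluster with Stmn1 and Cenpf of this list among its leading genes went from 1.05% to 0.601% of connective tissue cells. An erythroid-like cluster with Mki67 among its leading genes went from 5.68% to 1.77% of kept cells. It is not part of connective tissue, so its cells are not in these sums. How far the shift of the chondrocyte-like cluster, or background RNA from the erythroid-like cluster, accounts for the list was not tested. Matrix degrading enzymes and inhibitors were at 0.38 (percentile 100). Mmp2 (145 to 276 CPM) and the collagen-cleaving cathepsin Ctsk (171 to 312) were higher and Plau, a plasminogen activator (74.0 to 19.7), lower. That list holds proteases and protease inhibitors together, so its median gives no direction of matrix breakdown. Oxidative phosphorylation was at 0.38 and the antioxidant list at 0.30 with Gpx1 (242 to 397 CPM) and Ftl1 (916 to 1412) higher. Cartilage matrix was at -0.49. Degrading enzymes, oxidative phosphorylation and cartilage matrix were each outside the central 95% under 14 of 15 alternatives. Against the ratio in erythroid-like cells they were inside it, at 0.20 (percentile 96.2), 0.13 (88.1) and 0.17 (95.9). The other 17 lists were inside the central 95%. Chondrocyte transcription factors were at -0.33, lubrication at 0.04, hypertrophy at -0.20, fibrous matrix at 0.03, NF-kB at -0.18, interferon at -0.28 and complement at -0.09. TGF-beta and BMP were at -0.15, Wnt at -0.09, Hedgehog, Notch and YAP at -0.25, progenitor genes at -0.09, and senescence at 0.06. Hypoxia was at 0.05, unfolded protein response at -0.04, dissociation stress at -0.03, pain and nerve growth at -0.27 and growth factors at -0.11.

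Procr, the endothelial protein C receptor and a marker of several stem and progenitor cell types, was frequent in synovial lining-like, fibroblast-like and perivascular-like cells and sparse in the superficial class, in both libraries. Cells with at least 1 Procr UMI were 12.2% [11.4, 12.9] of connective tissue cells in sham (934 cells) and 14.1% [13.3, 14.8] in DMM (1192 cells), and 5.28% and 5.68% once each cell was thinned to 2000 UMIs. The summed expression was 34.9 and 34.6 CPM. Among lining-like cells the shares were 48.1% and 53.3% (18.0% and 22.6% thinned). Fibroblast-like cells were at 33.4% [30.8, 36.0] in sham and 25.5% [23.1, 28.0] in DMM (16.9% and 10.9% thinned). Within their clusters the shares were 49.0% and 52.5% (24.7% and 27.2% thinned) in the cluster led by Pi16 and Cd34 and 28.5% and 26.1% (14.1% and 12.2% thinned) in the one led by Ccl7. In the one led by Ctla2a they were 11.5% and 15.3%, but the summed expression was 40.6 and 34.2 CPM and thinned shares also turned lower in DMM. These clusters held different numbers of cells in sham and DMM. Perivascular-like cells had shares of 21.7% and 25.7% (16.1% and 15.6% thinned), with summed Procr at 265 and 170 CPM, but their 2 clusters went opposite ways. The larger went from 14.0% to 20.9% (119 to 134 CPM) and the one led by Rgs5, of 67 and 70 cells, from 58.2% to 42.9% (1053 to 290 CPM).

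In the superficial class 8.04% [6.74, 9.49] of sham and 8.21% [6.94, 9.64] of DMM cells had a Procr UMI (1.95% and 2.00% thinned; 0.446% and 0.899% with at least 2 UMIs), at medians of 7814 and 7861 UMIs. Chondrocyte-like cells, at 1.15% and 1.29% (0.186% and 0.0844% thinned) with medians of 13813 and 12402 UMIs, were near the background of erythroid-like cells, 0.833% and 0.888% at medians of 6984 and 7447.5 UMIs (0.240% and 0.157% thinned). Eng, which encodes CD105, a TGF-beta co-receptor, was found in 11.3% of sham and 12.5% of DMM connective tissue cells (2.92% and 3.36% thinned) and in 15.4% and 15.6% of superficial cells (3.71% and 4.12% thinned), against 5.76% and 6.07% of erythroid-like cells (0.799% and 1.42% thinned). Over both libraries, Eng ranged from 0.726 to 16.0 CPM between erythroid-like clusters, so its pooled share there cannot be read as a background level. In superficial cells the log2 ratio of DMM to sham was 0.12 [-0.22, 0.47] for Procr and 0.00 for Eng. Procr lies on chromosome 2 at 155751117 to 155755471 and Eng on the same chromosome at 32646595 to 32682669 (GRCm38). Among Procr cells of connective tissue, 17.8% [15.4, 20.4] in sham and 17.8% [15.7, 20.1] in DMM also had an Eng UMI, 166 and 212 cells, where independent detection would give 106 and 149. By class, 26 and 29 superficial cells had both, against 19.4 and 21.4. Within lining-like cells 48 and 112 cells had both, against 40.4 and 110, and within fibroblast-like cells 64 and 40, against 56.4 and 41.3.

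**Figure D3:**
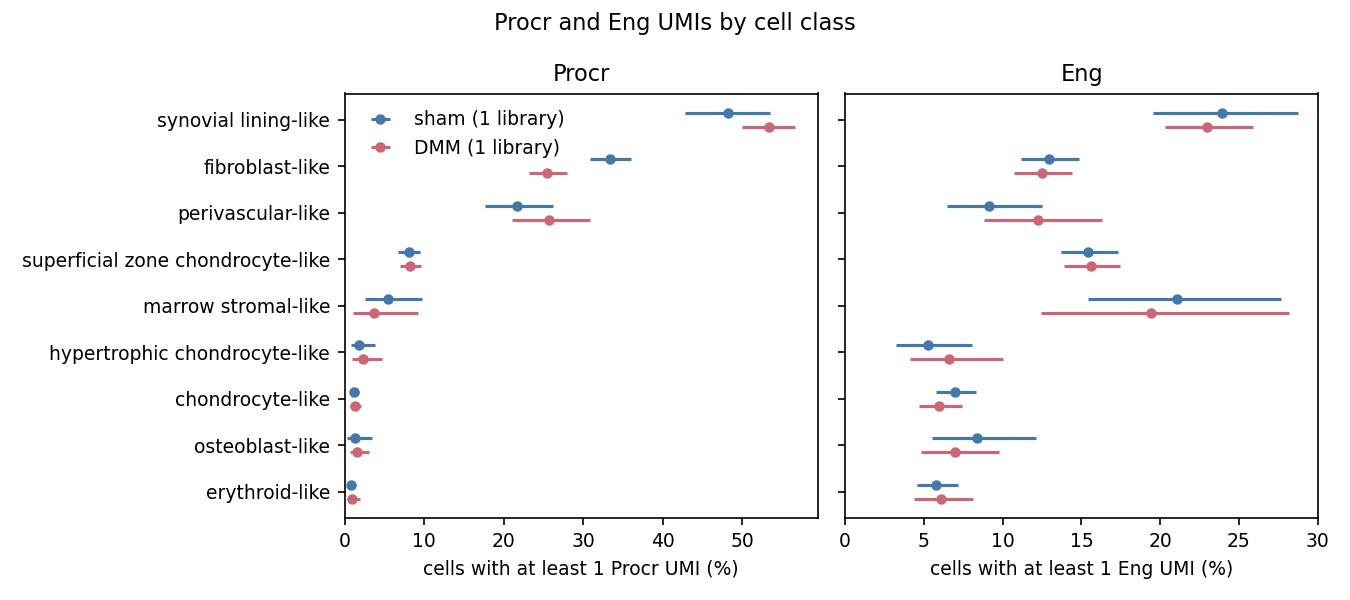
Share of cells (%, horizontal axes) with at least 1 UMI of Procr or of Eng in cell classes of the sham and DMM libraries (1 library each); points are shares and lines 95% Clopper-Pearson intervals. Procr was found in 48.1% and 53.3% of synovial lining-like cells, 8.04% and 8.21% of superficial zone chondrocyte-like cells and 0.833% and 0.888% of erythroid-like cells in sham and DMM.

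In both libraries, some genes of synovial lining and adventitial fibroblasts were higher in cells with Procr, and some genes of cartilage lower. The genes given are examples from the extremes of the ratios, and no gene list was run for this split. In connective tissue, Clic5 had a log2 ratio of cells with to cells without a Procr UMI of 3.90 in sham and 3.71 in DMM, Tspan15 (a tetraspanin of lining cells) 3.58 and 3.40, Cd55 (a complement inhibitor abundant in the lining) 3.23 and 3.01. Sema3a (an axon repellent) was at 3.12 and 2.92, and Pi16, a marker of adventitial fibroblasts, at 3.58 and 2.66. Matn3, a cartilage matrilin, was at -3.13 and -3.22, Mia at -2.90 and -2.91 and Runx3, a transcription factor of chondrocyte maturation, at -3.07 and -3.38. Of the Procr cells, 46.8% in sham and 27.8% in DMM were fibroblast-like, 18.1% and 40.3% lining-like and 13.5% and 11.5% superficial, so these ratios also carry class. Cells with Procr had medians of 8340.5 and 8944.5 UMIs and cells without 8227.5 and 7619.

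Within the superficial class, 126 sham and 137 DMM cells with a Procr UMI had less Spp1 (log2 -1.22 and -0.81) and more Vcan, a large proteoglycan of loose matrix (0.79 and 0.77), and more Sfn, a 14-3-3 protein (0.94 and 0.95), than the rest. Spp1, Vcan and Sfn each changed direction in 1 library or both under at least 1 alternative, Spp1 to 0.38 in sham with a Leiden resolution of 2.0. Procr cells without an Eng UMI, against those with one, had in connective tissue more Tagln (0.99 and 1.52) and Acta2 (0.85 and 1.66), contractile genes of perivascular cells, more F3, tissue factor (2.19 and 2.21), and more Penk, an opioid precursor (0.75 and 1.13). They had less Timp1, a protease inhibitor (-0.90 and -0.90), and Clic5 (-0.63 and -0.47). These connective tissue ratios also carry class. Among Procr cells, an Eng UMI was found in 10.8% of perivascular-like cells in sham and 6.10% in DMM, against 28.4% and 23.3% of lining-like cells. In the superficial class, 100 sham and 108 DMM Procr cells without Eng had more Thbs1 (1.46 and 1.15) and Penk (0.95 and 1.58) and less Stc2, a stress-induced hormone (-1.68 and -1.31), and Fn1, fibronectin (-1.05 and -0.87), than the 26 and 29 with Eng. Cells with Eng were deeper, at medians of 10204 and 11165.5 UMIs against 7979.5 and 8508.5 in connective tissue. Matching on depth was run only for Procr cells against cells without Procr, not for this split by Eng. Too few chondrocyte-like cells carried Procr (19 and 16) to be split.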

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

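The trend on gene span was noticed in the data, and its removal was added after results were seen. Of the predictions below, only those for that removal (oxidative phosphorylation and the inflammatory list) were written before the corrected values were seen; all others came after.

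Erythroid-like cells were found in libraries sorted against Ter119, at 13.9% of kept sham cells and 7.11% of kept DMM cells, and neutrophil-like cells in libraries sorted against CD45, at 0.695% and 0.463%. They stood out because the sort was directed against these blood cell markers, whose level on the surface of these cells is not known here. Erythroid-like cells served as a measure of background and as a comparison for shifts shared by cell types.

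Genes of oxidative phosphorylation, such as Cox7a2 and Ndufa2, were higher in DMM in both main classes, at medians of 0.31 and 0.28. The trend of ratios on gene span is argued against as the whole cause, because with it removed the lower of the percentiles in the main classes was still 99.9. Unspliced RNA, counted through introns of long genes, also falls short as the whole source of that trend in the main classes, because single-exon genes showed it there, with rho on transcript length of -0.35 [-0.50, -0.19] in superficial and -0.43 [-0.56, -0.28] in chondrocyte-like cells. These intervals come from 1000 resamples of genes, which are not independent replicates. Unspliced RNA stayed open in erythroid-like, osteoblast-like, perivascular-like, fibroblast-like, marrow stromal-like and tendon or ligament-like cells, where single-exon rho was 0.03, 0.16, -0.02, -0.19, -0.17 and -0.17 over 136, 57, 53, 107, 31 and 30 genes. A response of joint cells alone to the surgery cannot be told apart from a shift shared with erythroid-like cells. The list was at 0.25 over all of these, and at 0.10, 0.11, -0.035 and 0.23 (percentiles 98.5, 99.8, 85.5 and 98.8) within their 4 clusters, which were held in different proportions in sham and DMM. The pooled value was above all 4 cluster values, so it also carries that makeup, and the value of 0.23 rests on 9 of 22 genes. The list lay outside the central 95% of random lists in 3 of the 4 clusters and inside it in the other, so the explanation stayed open. Ratios also fell with transcript length, with rho of -0.59 in superficial and -0.54 in chondrocyte-like cells. Only the trend on gene span was removed, so a trend on transcript length was not tested as a cause. A difference between the library preparations may remain, and no test here separates it from DMM.

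The inflammatory list, led by Ccl2 and Ccl7, was lower in fibroblast-like cells of DMM, at -1.46. A different makeup of clusters is argued against as the whole cause by a median of -1.15 within the cluster led by Pi16 and Cd34, although the cluster led by Ctla2a showed 0.23. The span trend is argued against by -1.79 with it removed. The immediate early list, at -0.10, argues against a dissociation response only in the immediate early and heat shock genes it holds. That list shares no gene with the inflammatory or NF-kB lists, so it cannot decide on a dissociation response through those genes. A difference in preparation, such a response included, and an effect of DMM cannot be told apart from the value of -1.46, with 1 library per group.

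Synovial lining-like cells were 2.32-fold more frequent in DMM. A lower yield of chondrocytes would raise other classes alike, yet they moved both ways. Log2 ratios of shares were -0.40 for perivascular-like, -0.15 for fibroblast-like, -0.92 for marrow stromal-like and -1.10 for tendon or ligament-like cells. As classes, osteoblast-like cells (0.47) and clusters of no class (0.40) rose less than lining-like cells (1.22), but some single clusters rose more. The fibroblast-like cluster led by Ctla2a rose by 1.42, an osteoblast-like cluster by 1.31 and the unnamed cluster led by S100a4 and Tnn by 1.49. The unnamed cluster led by Postn and Mmp13 rose by 0.86. The other osteoblast-like cluster was at -1.14, the other fibroblast-like clusters at -0.85 and -1.13, and the other unnamed clusters at 0.014, -0.31 and -0.38. A lower yield is thus argued against only as the whole cause. Whether the dissection took more synovium or the joints held more lining cells cannot be told apart from the ratio of 1.22 on the log2 scale, since each group had 1 library.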

How the results depend on the processing

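Tests with the gene span trend removed, with the erythroid-like ratio subtracted and without the top cell were chosen only after results were seen. The span trend was noticed in the data, while predictions for the effect of its removal on oxidative phosphorylation and on the inflammatory list were written before the corrected values were seen. No paired analysis was possible because each group had 1 library of pooled mice. Values below are log2 ratios, and the cause was not tested for any of them.

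A change of sign was counted where the reported interval excluded 0 or, for lists, where the reported median was outside the central 95% of random lists. It was seen in 4 of 54 ratios of shares and in 0 of 50 for Procr and Eng shares. It was seen in 3 of 236 medians of the followed lists, 3 of 1193 other medians, 5 of 780 named gene ratios and 36 of 1318 ratios between Procr sets. Subtraction of the erythroid-like ratio was run for lists and is not part of the 780 gene ratios. The superficial Procr share, whose interval held 0, ranged from -0.21 with a minimum of 1000 genes to 1.01 with at least 2 UMIs. Hypoxia and glycolysis in superficial cells, and cell cycle, lipid and antioxidant lists in connective tissue, were outside the central 95% of random lists under all 15 alternatives, and the inflammatory list in connective tissue under all 14. With doublets kept and at a Leiden resolution of 2.0 no cluster was hypertrophic, so those values are missing.

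With a minimum of 1000 genes, shares were at -0.47 for superficial and -1.15 for osteoblast-like cells. Superficial lists were at -0.30 (Wnt), 0.54 (hypoxia and glycolysis), 0.17 (antioxidant) and -1.04 (pain and nerve growth), and Npy at -0.98. Between superficial cells with and without Procr, Msmp in DMM was at 1.54, Chil1 in sham at 0.68, Vcan in DMM at -0.11 and Sfn in sham at -1.22.

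With a minimum of 200 genes, the superficial hypoxia and glycolysis list was at 0.49. For Procr against none in superficial DMM cells, Msmp was at 0.70 and Serpina1b at 0.081; for Procr without against with Eng, Phlda3 in sham was at -0.35 and Msmp in DMM at -4.22.

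At most 5% mitochondrial UMIs gave a fibroblast-like share of 0.043, a superficial hypoxia and glycolysis list of 0.48 and a fibroblast-like cartilage matrix list of 0.059. Superficial Msmp in DMM was at 0.82 for Procr against none and -3.60 without against with Eng, where Phlda3 in sham was at -0.35. At most 20% mitochondrial UMIs gave a superficial hypoxia and glycolysis list of 0.48 and Msmp in DMM at 0.87 and -3.64 in those splits.

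With doublets kept, cell cycle in connective tissue was at -0.65, superficial hypoxia and glycolysis at 0.50, chondrocyte-like pain and nerve growth at -0.46, superficial Msmp in DMM at 0.72 (Procr against none) and -4.28 (without against with Eng), and connective tissue Serpina1a in DMM at -0.27 (without against with Eng).

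At a Leiden resolution of 0.5 the osteoblast-like share was at -1.14, superficial hypoxia and glycolysis at 0.48, and Msmp in DMM at 0.82 and -3.62 in the same splits. At a Leiden resolution of 2.0 the superficial share was at -0.50, the osteoblast-like share at 1.07, superficial Il11 at -0.68, oxidative phosphorylation at 0.36 and pain and nerve growth at -0.99. For superficial Procr against none, sham values were 0.38 for Spp1, 0.42 for Msmp, 0.29 for Ddit4l and -0.83 for Sfn, and DMM values -0.24 for St3gal1, -0.21 for Vcan and -0.15 for Sfn.

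With variable genes centred by library, shares were at -1.04 (superficial) and 0.032 (hypertrophic). Superficial Npy was at -1.79, Il11 at -2.68 and Fxyd2 at -1.95. Superficial lists were at -0.045 (Wnt), 0.15 (hypoxia and glycolysis), 0.27 (oxidative phosphorylation), -0.12 (antioxidant) and -0.92 (pain and nerve growth). For Procr against none in DMM, Msmp was at 1.65 and Serpina1b at 1.49.

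With median-of-ratios scaling, connective tissue lists were at -0.36 (cartilage matrix), 0.52 (degrading enzymes), -0.64 (inflammatory), -0.34 (cell cycle), 0.51 (oxidative phosphorylation), 0.43 (antioxidant) and -0.40 (lipid). Superficial lists were at 0.46 (hypoxia and glycolysis), 0.45 (oxidative phosphorylation) and 0.43 (antioxidant), chondrocyte-like at 0.43 (oxidative phosphorylation) and 0.36 (antioxidant).

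With CPM without mitochondrial, ribosomal and 20 abundant genes, connective tissue lists were at -0.40 (cartilage matrix), 0.47 (degrading enzymes), -0.69 (inflammatory), 0.47 (oxidative phosphorylation), 0.38 (antioxidant) and -0.45 (lipid). Oxidative phosphorylation and antioxidant lists were at 0.41 and 0.38 in superficial and 0.39 and 0.33 in chondrocyte-like cells.

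Thinned to 2000 UMIs, connective tissue lists were at -0.43 (cartilage matrix), 0.23 (degrading enzymes), -0.80 (inflammatory), 0.34 (antioxidant) and -0.47 (lipid), superficial oxidative phosphorylation at 0.36, and chondrocyte-like lists at -0.38 (inflammatory), 0.29 (antioxidant) and -0.46 (pain and nerve growth). The Procr share in fibroblast-like cells was at -0.63. For superficial Procr against none, sham values were 0.14 (Msmp), 0.13 (S100a4), -0.042 (Hbs1l) and -0.58 (Loxl2), and DMM values 0.63 (Syn3), -0.26 (Hbs1l) and -0.14 (Vcan).

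List members with at least 10 UMIs gave superficial Wnt signalling at -0.19, and at least 200 UMIs the chondrocyte-like inflammatory list at -0.17. Counting at least 2 UMIs gave a superficial Procr share ratio of 1.01. With Procr cells matched on total UMIs, superficial Msmp in sham was at 0.23 and St3gal1 in DMM at -0.17.

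With the gene span trend removed, connective tissue lists were at -0.35 (cartilage matrix) and -0.46 (lipid), superficial lists at -0.22 (Wnt), 0.23 (oxidative phosphorylation), 0.21 (antioxidant) and -0.19 (pain and nerve growth), and chondrocyte-like lists at 0.16 (antioxidant) and -0.44 (pain and nerve growth). Superficial Wnt and pain and the chondrocyte-like antioxidant list were then inside the central 95%.

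With the erythroid-like ratio subtracted, connective tissue lists were at 0.17 (cartilage matrix), 0.20 (degrading enzymes), 0.13 (oxidative phosphorylation) and -0.11 (lipid), superficial lists at 0.24 (Wnt), 0.066 (oxidative phosphorylation) and 0.23 (antioxidant), chondrocyte-like lists at 0.030 (oxidative phosphorylation) and 0.14 (antioxidant), and fibroblast-like lists at 0.36 (cartilage matrix) and -0.19 (fibrous matrix). It left cartilage matrix, degrading enzymes and oxidative phosphorylation in connective tissue, Wnt and oxidative phosphorylation in superficial cells, and oxidative phosphorylation and the antioxidant list in chondrocyte-like cells inside the central 95% of random lists. This subtraction compares 2 ratios and does not remove background RNA, so its changes of sign show nothing about background. For superficial Wnt only 3 genes had enough UMIs in erythroid-like cells.

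All but 1 of the reversed ratios between Procr sets lie in the superficial sets, with 126 sham and 137 DMM cells.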

Other observations

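None of the tests below was planned for these classes, and all were looked at only after the results of the main classes were seen.

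In fibroblast-like cells the chemokines Ccl2, Ccl7 and Ccl11, which draw monocytes and eosinophils, and Lif, a cytokine of the IL-6 family, were lower in DMM. Ccl2 was at 479 CPM in sham and 59.7 in DMM, Ccl7 at 781 and 99.8, Ccl11 at 34.8 and 5.36, and Lif at 64.7 and 11.5; the inflammatory list was at -1.46 with 17 of 19 genes lower. Within clusters, Ccl2 was at 1077 and 219 CPM in the cluster it leads with Ccl7, at 94.9 and 25.4 in the cluster led by Pi16, and at 15.3 and 18.1 in the cluster led by Ctla2a. The NF-kB list was at -0.65, with all 14 genes lower, including the adhesion molecules Vcam1 (312 to 153 CPM) and Icam1 (254 to 148), the inhibitor Tnfaip3 (41.8 to 21.2) and the transcription factor Cebpb (1128 to 637). The interferon list was at -0.64, with the antiviral gene Ifit1 at 11.7 and 1.07 CPM. These values cover all fibroblast-like cells, whose clusters differed in size between libraries.

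In synovial lining-like cells the hypertrophy and mineralization list was at 0.60 (percentile 100), the dissociation list at -0.41 (percentile 0.10) and the pain and nerve growth list at -0.63 (percentile 0.14). Perivascular-like cells had fibrous matrix at 0.64, with 0.18 and 0.53 in their 2 clusters; the same list was at -0.06, 0.66, 1.42 and 1.21 in the 4 erythroid-like clusters, so background RNA moved the same way in 3 of them. Osteoblast-like cells had the inflammatory list at -1.41 over 6 genes (-0.82 and -1.84 in their 2 clusters), hypoxia and glycolysis at 0.44 (0.25 and 0.37) and senescence at 0.49 (0.41 and -0.00). These 2 clusters held 137 and 162 cells in sham and 376 and 81 in DMM, so the class values also carry that makeup.

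The ratio of DMM to sham fell with gene span in these 4 classes. Spearman rho was -0.59 in superficial, -0.57 in chondrocyte-like, -0.51 in fibroblast-like and -0.52 in erythroid-like cells, over 8600, 9633, 8018 and 6238 genes, which are not independent replicates.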
